A study of Homo sapiens with 360 samples.

How the data were processed

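Gene expression was measured in HepaRG cells with Affymetrix U133 Plus 2.0 arrays, 1 array per RNA sample. Per the labels' protocols, cells were cultured with dimethylsulfoxide before exposure, exposed to each compound for 24 h and 72 h at the concentration that lowered viability by 10%, and collected in at least 3 independent experiments. The deposited table holds 1 column per sample and 1 intensity per gene on a linear scale, as the values show. GCRMA, which corrects array background from probe sequence, normalizes between arrays and summarises probe sets, is named in the submitters' processing notes. Its version, settings and the probe set definition were not given in the sources used here. The features are Ensembl gene IDs with 1 probe set per gene, so averaging several probe sets of a gene, an alternative written down beforehand, changes nothing. The design written beforehand allowed for log2 values, and since the deposited values are linear intensities, log2 was taken first. The number of columns that belong to no sample was 0.

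Per the series text, control arrays were normalized again together with different sample groups, so several control columns hold the same array. By their labels the 216 control columns come from 80 distinct control arrays. The 222 pairs of columns that share an array had a lowest correlation of 0.998 and a median SD of log2 differences of 0.176. Different arrays of one experiment code had a median of 0.405 and a lowest value of 0.141. By the labels no control array occurs more than once in the fits of single comparisons, time differences and laboratory differences, and 0 columns were identical. The exception is the interaction fit of the 2 isomers, whose 12 columns come from 10 arrays at each time, with 2 control arrays each standing in the controls of both isomers. For this reason each compound was compared only with its own controls. Overlaps of called genes are reported only between comparisons that share no control array. Class tests and class placement use compounds that share control arrays, and placement is also given with such compounds removed.

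Groups, replicate numbers and times were taken from the labels. In the panel each replicate number is also an experiment code. In the interlaboratory part the code was read from the sample titles, and HUL and VUB have codes with more than 1 control array. The labels do not say whether those arrays come from separate cultures. Where they do not, p-values measure only the spread between these samples, which may be technical.

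Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level) on log2 intensities. A gene was tested when it exceeded 5 on the log2 scale in at least 3 arrays of the comparison, and called at a Benjamini-Hochberg adjusted p under 0.05. Each of the 30 panel and 18 interlaboratory comparisons was fitted alone, with no block. Laboratories were compared by a limma F test of equal treated minus control differences with an intercept per laboratory. Class tests used the 15 mean log2 changes per time, over genes that passed the filter in at least 5 comparisons. Class assignment left out each compound in turn and used 1000 permutations of class names. The isomers were compared on the 3 differences per replicate number. Time differences were interaction contrasts over the columns of one compound. These designs, the filter and the thresholds were set before the data were examined, apart from the time differences of the coded compounds. Control labels carry different tokens, whose meaning was not given in the sources used here and which were not used as groups.

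Whether replicate codes pair the columns was checked by the correlation of deviations from the group means. The criterion was a correlation over 0.1 in each pair, and both fits had been computed when it was applied. It was met in 28 of 30 panel comparisons (not AMQ at 72 h, not HHC at 24 h) and in 8 of 18 interlaboratory ones. Those 8 were D and E at 24 h and E at 72 h in BPI, D at both times and F at 24 h in HUL, and D and F at 24 h in VUB. The median correlation of columns with one code was 0.627 in the panel, against -0.245 for other codes, and 0.197 against -0.046 in the interlaboratory part. Deviations from a group mean cancel over the group, so positive values within a code bring negative values for other codes. The negative values therefore add no separate support for pairing.

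The rule for named genes took the largest changes among called genes, for genes called in all 3 laboratories by their mean log2 change. The reference table given with the data paired 0 of the 18919 gene IDs with a name, and the files do not pair them, so only the 2 genes with the largest mean rise and the 2 with the largest mean fall over the 6 settings of coded compounds were named, which is fewer than the rule allows. The rank depends on values near background: with values under the floor set to the floor, ENSG00000140505 ranked 4 by mean rise among the 1562 genes called in all 3 laboratories, while the other 3 kept their places. Gene lists for pathways and cell types had been fixed beforehand by gene symbol, and tests of those lists could not be run without names.

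Each kind of fit was tested on simulated data with the measured spread, in which 200 genes were changed 2-fold. Without a block, 73.5% of changed genes were recovered with the spread of NMP at 24 h, 53.5% with that of TRI at 72 h and 33% with that of TRI at 24 h, and with the block 75.5%, 84% and 47.5%. The isomer fit recovered 55% at 24 h and 73.5% at 72 h. The share of false genes among those called was 0% to 6.82% over these simulations. Alternatives were the replicate block, quantile normalization of the columns of a comparison, no filter, leaving out each column in turn, controls averaged per code, controls limited to shared codes, rank correlation and, for the 4 named genes, values under the floor set to the floor. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.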

Results

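HepaRG is a human hepatoma-derived cell line that differentiates in culture into hepatocyte-like and biliary-like cells. Differentiated HepaRG cells were exposed to single compounds for 24 h or 72 h, and total RNA was measured on Affymetrix oligonucleotide arrays. The table analysed here holds 360 columns of intensities for 18919 genes. Of these, 144 belong to treated cells and 216 to control cells. A panel of 15 named compounds was run in 1 laboratory (VUB), with 3 treated and 3 control columns per compound and time. In an interlaboratory part, 3 compounds known only by the codes D, E and F were run in the laboratories BPI, HUL and VUB, with 3 treated columns each and 6, 6 and 9 control columns. The median intensity of a column lay between 9.42 and 14.5, and 5935 to 7374 genes per column exceeded the floor of 5 on the log2 scale. The precision of each comparison is limited by the number of arrays.

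The panel was split by the series into 3 classes of 5 compounds, named GTX, NGTX and NC, which in this field stand for genotoxic carcinogens, non-genotoxic carcinogens and non-carcinogens. The GTX compounds and their doses were N-nitrosomorpholine (NMP, 0.216 mM), hydroquinone (HQO, 0.15 mM), hydrazine dihydrochloride (HHC, 0.86 mM), 2-acetylaminofluorene (TAF, 0.0408 mM) and a heterocyclic amine of the imidazoquinoline family (AMQ, 0.003 mM). NGTX held the mycotoxin fumonisin B1 (FMB, 2.4 mM), the immunosuppressant cyclosporine A (CsA, 0.0026 mM), acetamide (ACE, 5.9, with no unit given), the plasticiser diethylhexyl phthalate (DHP, 10 mM) and ethanol (ETH, 10 mM). NC held 4-acetylaminofluorene (FAF, 0.22, with no unit given), D,L-menthol (DLM, 1.2 mM), benzoin (BEN, 0.345 mM), benzyl alcohol (BEA, 6.5 mM) and the antimicrobial triclosan (TRI, 0.022 mM). By the protocols each dose was the concentration that lowered viability by 10% in a dye reduction test. The compounds were thus meant to be at matched toxicity and not at matched concentration, and viability was not among the values analysed here. Doses and identities of D, E and F were not given in the sources used here.

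The first question was which compounds changed the transcriptome of these cells. Hydrazine dihydrochloride at 72 h gave the largest response of the panel, with 561 genes higher and 507 lower than in its controls, 408 of the 1068 by at least 2-fold. AMQ changed 91 genes at 24 h (40 higher, 51 lower) and 65 at 72 h (22 higher, 43 lower). The isomers TAF and FAF followed at 24 h, with 12 genes (9 higher, 3 lower) and 14 genes (7 higher, 7 lower). At 72 h TAF raised 2 genes, FAF 1 and BEN 1, and FMB raised 1 gene at 24 h. With no filter FAF at 24 h had 4 genes, and after quantile normalization HHC at 24 h had 2 in place of 0. In the remaining 21 of the 30 comparisons limma called 0 genes at a Benjamini-Hochberg adjusted p under 0.05. The number of genes at an unadjusted p under 0.05 in those ran from 1 of 6757 (TRI, 24 h) to 714 of 7132 (FMB, 72 h). A share of 0.05 is expected where no gene changes. The count of TRI lies far below it, so such zeros do not show a lack of response.

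In 28 of these 30 comparisons the treated and control columns of one replicate number deviated together, and with the replicate as a block the counts rose. HHC at 72 h then had 2544 genes (1239 higher, 1305 lower) and AMQ at 24 h 1537 (834 higher, 703 lower). FMB at 72 h, with 0 genes without the block, had 986 with it, 381 higher and 605 lower. DLM at 72 h rose from 0 to 194 genes (107 higher, 87 lower) and HQO at 72 h from 0 to 73 (15 higher, 58 lower). The block gave 299 genes for TAF at 24 h and 37 at 72 h, 77 and 50 for FAF, 120 for BEN at 72 h and 25 for FMB at 24 h. The other 18 comparisons stayed at 0 genes in both fits, which includes both times of NMP, ACE, CsA, DHP, ETH, BEA and TRI. Single columns weighed heavily in these small groups. HHC at 72 h fell to 340 genes without control replicate 1 and by over 1.5 times without any other single column but control replicate 3. AMQ had 14 to 54 genes at 24 h and 12 to 106 at 72 h when single columns were left out, with the lowest 24 h count without control replicate 1.

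**Figure D1:**
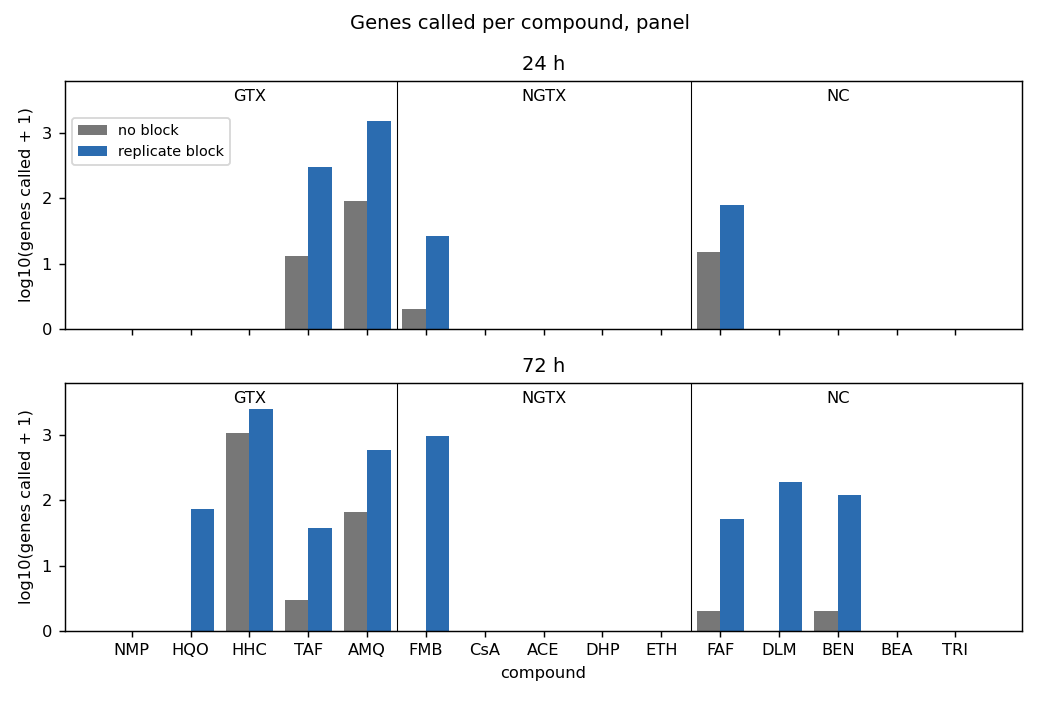
Number of genes called per panel compound at 24 h and 72 h, as log10 of the count plus 1, without a block (grey) and with the replicate as a block (blue), with compounds ordered by class. HHC at 72 h has the tallest bar in both fits, with 1068 and 2544 genes, and no bar is seen for NMP, ACE, CsA, DHP, ETH, BEA or TRI.

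Replicate 1 stood apart in 9 of the 30 panel comparisons by a limit of 2 set after the values were seen: the root mean square (RMS) log2 difference within its pair was 2.13 to 5.45 times that of the next pair. In the rest that ratio reached at most 1.56. The comparisons were BEN, BEA, CsA, HQO, TRI and HHC at 24 h, where the treated array departed, and BEA, CsA and DHP at 72 h, where the shared control array did. Without that pair the block fit called 470 genes for BEA at 24 h, 124 for BEN at 24 h, 524 for HHC at 24 h (where the pairs had not met the criterion) and 200 for CsA at 72 h, each from 0. DHP at 72 h then had 2 genes and HQO at 24 h had 1, while BEA at 72 h, CsA at 24 h and TRI at 24 h stayed at 0. These fits rest on 2 pairs, with the pair left out chosen from the data. Without the block all 9 comparisons stayed at 0 when that pair was left out. In simulated data with the spread of CsA at 72 h, 0% of genes changed 2-fold were recovered, so a count of 0 there does not bound the response.

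**Figure D2:**
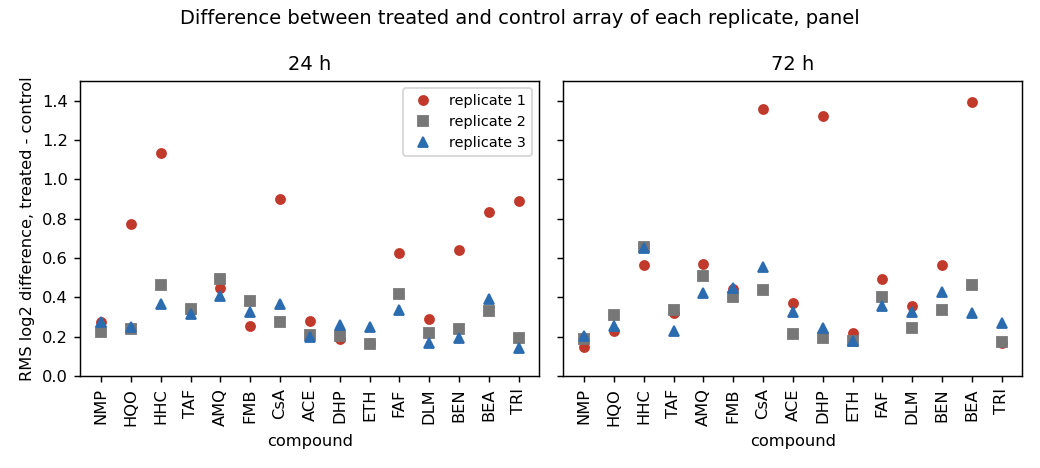
RMS log2 difference between the treated and the control array of each replicate number, per panel compound and time, with replicates 1, 2 and 3 as circles, squares and triangles. Replicate 1 lies apart in 9 of the 30 comparisons, with 1.39 for BEA at 72 h against 0.465 and 0.318 in the other 2 pairs.

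The genes are listed by Ensembl gene ID, and the sources used here do not pair these IDs with names, so 2 IDs that rose and 2 that fell are given. ENSG00000140465 had the largest rise of any gene called for a coded compound in all 3 laboratories. AMQ raised it at 24 h from 3.00 ± 0.44 to 13.61 ± 0.07 on the log2 scale (mean ± SD, n = 3 each), TAF from 3.07 ± 0.20 to 13.40 ± 0.17 and FAF from 3.23 ± 0.06 to 12.89 ± 0.36. At 72 h the log2 changes with their standard errors were 11.16 ± 0.14 for AMQ, 9.07 ± 0.38 for TAF and 9.90 ± 0.50 for FAF. HQO at 72 h (4.33 ± 0.25, limma adjusted p = 0.00118) and FMB at 24 h (3.59 ± 0.37, limma adjusted p = 0.0398) passed with the block alone. ENSG00000140505 rose at 24 h by 8.00 ± 0.24 with AMQ, 7.29 ± 0.39 with TAF and 5.00 ± 0.39 with FAF, and at 72 h by 8.95 ± 0.26 with AMQ. With TAF at 72 h it passed with the block alone (4.64 ± 0.66, limma adjusted p = 0.0436), and with FAF at 72 h it did not pass (5.73 ± 1.23, limma adjusted p = 0.552, and 0.0613 with the block). The control levels of both IDs lay under the floor of 5 on the log2 scale, so these changes are not exact sizes and depend on the background correction of the array values.

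ENSG00000118520 was at 10.96 ± 0.53 in the controls of AMQ at 72 h and at 7.44 ± 0.59 in the treated cells, with a log2 change of -3.52 ± 0.36 and a limma adjusted p of 0.0139. No other panel compound passed for this gene without the block. With it the gene was also lower with AMQ (-1.07 ± 0.09) and TAF (-0.66 ± 0.07) at 24 h and with HHC (-1.35 ± 0.12) and HQO (-0.79 ± 0.09) at 72 h. It was higher with FMB (0.88 ± 0.10) and DLM (0.58 ± 0.09) at 72 h with the block, and the limma adjusted p-values of these 6 were 0.000807 to 0.0356. ENSG00000187758 had its largest panel change with BEN at 72 h (-3.54 ± 0.76), which did not pass (limma adjusted p = 0.210, and 0.0525 with the block). It fell with HHC at 72 h (-2.82 ± 0.45, limma adjusted p = 0.0107) and with TAF at 24 h (-1.80 ± 0.14, limma adjusted p = 0.00739). The block added AMQ (-0.91 ± 0.19) and FAF (-1.44 ± 0.19) at 24 h and HQO (-1.48 ± 0.20) and TAF (-0.92 ± 0.10) at 72 h, with limma adjusted p-values of at most 0.0492.

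The series asks whether such responses sort compounds into the 3 classes. Between class means, with the compound as the replicate (n = 5 per class), limma called 0 genes in each of the 6 tests. At 24 h an unadjusted p under 0.05 was met by 723 of 7147 genes for GTX against NGTX, 386 for GTX against NC and 185 for NGTX against NC. At 72 h the numbers were 1189, 699 and 109 of 7302 genes, with smallest adjusted p-values of 0.177, 0.503 and 0.998. In simulated data with the spread of these compounds, 88% (24 h) and 82% (72 h) of genes shifted 2-fold between GTX and NC were recovered. The simulation drew compounds independently, although they share control arrays, and shifted all 5 GTX compounds alike. It therefore does not bound a smaller shift or a shift in only some compounds of a class. When each compound in turn was assigned to the class whose mean response it correlated with best, 5 of 15 at 24 h and 7 of 15 at 72 h fell in their own class. Permuted class names gave 4.71 and 4.74 on average, with one-sided permutation p-values of 0.540 and 0.212. At both times AMQ and TAF were placed in GTX and BEN in NC. FAF, an NC compound, was placed in GTX at 24 h and in NC at 72 h, and HHC, a GTX compound, was placed in NC at both times. With compounds that share a control array removed from the class means, 3 compounds at 24 h and 8 at 72 h fell in their own class, and AMQ at 24 h was placed in NC and BEN in GTX. With replicates 2 and 3 only, AMQ and TAF at 24 h were placed in NC and FAF at 72 h in GTX.

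TAF and FAF carry the acetylamino group at position 2 and position 4 of fluorene, and the series places the first in GTX and the second in NC. At 24 h their responses differed for 1 gene, which was lower in TAF. At 72 h they differed for 321 genes, 225 higher and 96 lower in TAF (limma on the 3 differences per replicate number), and for 178 with no filter. The fit with an interaction term, with no replicate block, called 0 genes at both times, and treated columns compared directly also gave 0 at both times. The interaction fit takes 12 columns from 10 arrays as if independent, since TAF and FAF share 2 control arrays at each time. The 72 h count was 10 without replicate 1, 0 without replicate 2 and 718 without replicate 3, and the 24 h count was 181, 2 and 68. For the typical gene the difference between the isomers was known to within ± 0.33 at 24 h and ± 0.30 at 72 h on the log2 scale (median half-width of the 95% interval). The RMS log2 change per pair was 0.328 ± 0.012 for TAF and 0.459 ± 0.149 for FAF at 24 h (SD, n = 3, two-sided exact permutation p = 0.2). It was 0.293 ± 0.058 and 0.416 ± 0.070 at 72 h, with an exact p of 0.1, the smallest that 3 against 3 allow. Both tests exchanged the values freely, although they pair by replicate number and the isomers share 2 control arrays at each time. The doses, 0.0408 mM and 0.22 with no unit given, differed as numbers.

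For the panel, 24 h and 72 h responses were also set against each other. HHC had 9 genes whose response differed between the times (8 with the higher change at 72 h, 1 with the lower). This count was 2 to 24 when single columns were left out, the highest without treated replicate 1 at 24 h. The other 14 compounds had 0 such genes by limma, with 4 (TRI) to 282 (BEA) genes at an unadjusted p under 0.05, and with the block, among the compounds whose pairs met the criterion at both times, FMB had 1 and the rest had 0. In simulated data with the spread of TRI, 16% of genes whose response differed 2-fold were recovered, so these zeros leave room for differences. Counts of called genes were higher at 72 h for 2 compounds, higher at 24 h for 4 and equal for 9. The mean difference in log10(count + 1) was 0.09 ± 0.86 (SD, n = 15), with a two-sided exact sign-flip permutation p of 0.9375. With the block the count was higher at 72 h for 5 compounds, higher at 24 h for 3 and equal for 7, and the mean difference was 0.648 ± 1.25 (exact permutation p = 0.0625). That value rests partly on counts of 0 in comparisons with a departing pair: with such pairs left out it was 0.314 ± 1.28 (exact permutation p = 0.354), with 6 compounds higher at 72 h and 5 at 24 h. Over the 13 compounds whose pairs met the criterion at both times it was 0.518 with all pairs (exact permutation p = 0.125) and 0.342 without the departing ones (exact permutation p = 0.367).

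In the interlaboratory part each laboratory exposed its own cultures to D, E and F, which asks whether one compound gives one response in different hands. Compound D changed 93 genes in BPI, 792 in HUL and 33 in VUB at 24 h, and 2072, 3154 and 994 at 72 h. At 24 h 17 genes were called in all 3 laboratories in one direction (11 higher, 6 lower), against 0.0115 expected from independent lists. At 72 h there were 774 (439 higher, 335 lower), against 33.1 expected, and 451 of them averaged at least 2-fold. With the replicate code as a block, supported by the check of the pairs in all 3 laboratories at 24 h, D had 364, 1858 and 293 genes at 24 h and 134 in common. The gene with the largest rise was ENSG00000140465, with control means of 2.56 to 3.29, under the floor of 5. Its log2 change at 24 h was 9.31 ± 0.47 in BPI, 9.54 ± 0.25 in HUL and 9.25 ± 0.18 in VUB (SE, 3 treated columns), and with values under the floor set to the floor it was 7.58, 7.10 and 7.08, a setting chosen after the data were seen. It was still up by 7.56 to 8.97 at 72 h. ENSG00000140505 rose at 24 h by 6.88 ± 0.26, 7.13 ± 0.22 and 6.09 ± 0.34, or by 4.78, 5.22 and 4.05 with values set to the floor. At 72 h it was called in HUL alone (3.72 ± 0.25), and with changes of 2.98 in BPI and 2.34 in VUB it did not pass the filter there. ENSG00000118520 fell with D at 72 h in each laboratory, with log2 changes of -3.88 in BPI, -5.36 in HUL and -1.84 in VUB. At 24 h it was called lower in HUL (-0.57 ± 0.10) and VUB (-0.55 ± 0.10) with the block alone. Leaving out single columns gave 28 (without treated replicate 2) to 230 genes (without control replicate 2) for BPI at 24 h. For VUB it gave 14 (without treated replicate 1) to 82 (without control replicate 9) at 24 h, and 373 at 72 h without treated replicate 3. With no filter HUL at 72 h had 4757 genes, VUB at 24 h 56 and the list in common at 24 h 34. Control columns averaged per code gave 233 genes in HUL and 15 in VUB at 24 h and 590 in VUB at 72 h. Controls of shared codes alone gave 20 and 1209 in BPI at the 2 times and 55 in VUB at 24 h.

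Compound E changed 1609 genes in BPI, 2350 in HUL and 31 in VUB at 24 h, and 2953, 1542 and 831 at 72 h. Called in all 3 were 22 genes at 24 h (8 higher, 14 lower, 0.591 expected) and 497 at 72 h (236 higher, 261 lower, 19.1 expected). The VUB numbers depended on treated replicate 3. Without it VUB had 1233 and 2309 genes, and the common list had 608 genes at 24 h (332 higher, 276 lower) and 884 at 72 h (448 higher, 436 lower). Without VUB treated replicate 1, or without replicate 2, VUB had 0 genes at both times. With control columns averaged per code, or limited to shared codes, VUB also had 0 genes at both times, so that no gene could be called in all 3 laboratories. Averaging gave 1357 and 866 genes in HUL, and controls of shared codes gave 295 and 1666 in BPI. With the block, BPI had 179 genes at 24 h. After quantile normalization VUB at 24 h had 73 genes and the common list 54. ENSG00000187758 fell with E at 72 h, with log2 changes of -6.82 ± 0.64 in BPI, -5.91 ± 0.19 in HUL and -2.40 ± 0.39 in VUB (SE). The treated level in BPI, 4.56 ± 1.97 (SD), lay under the floor, and with values set to the floor the changes were -5.91, -5.89 and -2.40.

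Compound F gave its large response at 24 h, with 1887 genes in BPI, 1458 in HUL and 2316 in VUB. In all 3 laboratories 742 genes were called in one direction (335 higher, 407 lower), against 30.8 expected. At 72 h F had 1 gene in BPI, 351 in HUL and 275 in VUB, and 1 gene in common, which was lower. In simulated data with the spread of F at 72 h, 74% (BPI) and 81.5% (HUL) of genes changed 2-fold were recovered. ENSG00000118520 fell with F at 24 h from 11.75 ± 0.32 to 4.29 ± 1.35 in BPI, from 11.89 ± 0.30 to 8.56 ± 0.20 in HUL and from 11.60 ± 0.53 to 5.00 ± 0.76 in VUB (mean ± SD). Treated values in BPI and VUB reached under the floor, and with values set to it the changes were -6.48, -3.33 and -6.31. At 72 h its log2 changes were -0.63, -0.55 and -0.60, none of them called. VUB at 72 h had 1079 genes without treated replicate 3 and 82 without treated replicate 1, and HUL had 70 without treated replicate 1. With no filter HUL at 72 h had 221 genes and BPI and the common list 0, and quantile normalization gave 3 in BPI and 2 in common. Control columns averaged per code gave 722 and 134 genes in HUL at the 2 times and 67 in VUB at 72 h.

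**Figure D3:**
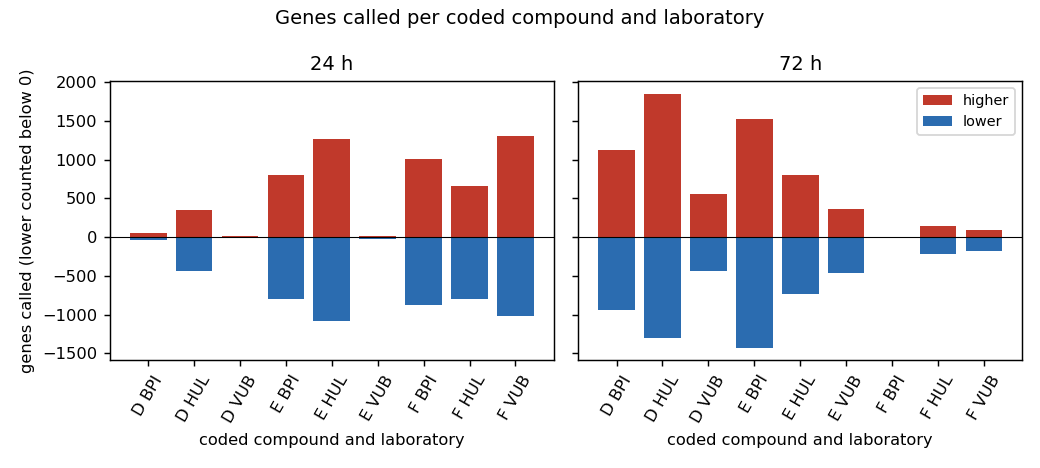
Number of genes called higher (red, above 0) and lower (blue, drawn below 0) for D, E and F in each laboratory at 24 h and 72 h. F has 1458 to 2316 genes at 24 h and 1 to 351 at 72 h, and D rises from 33 to 792 genes to 994 to 3154.

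Opposite calls were few. Of the genes called in at least 2 laboratories, opposite signs were found for 0 of 75 with D, 0 of 1132 with E and 7 of 1544 with F at 24 h. At 72 h they were found for 2 of 1899 with D, 1 of 1372 with E and 0 of 111 with F. Across 5893 genes at 24 h, log2 changes of one compound in different laboratories correlated with a mean Pearson r of 0.763, against 0.239 between different compounds. At 72 h, over 6156 genes, the means were 0.728 and 0.226. The differences of 0.524 and 0.502 each had a two-sided exact permutation p of 0.0278, the smallest that the 36 arrangements of compound names can give. Genes are not independent replicates, and the test permutes compounds. F at 72 h had the lowest values, 0.377 to 0.655, while D at 72 h had 0.812 to 0.933. E against F in different laboratories gave 0.271 to 0.505 at 72 h, so F was not clearly set apart from E there.

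**Figure D4:**
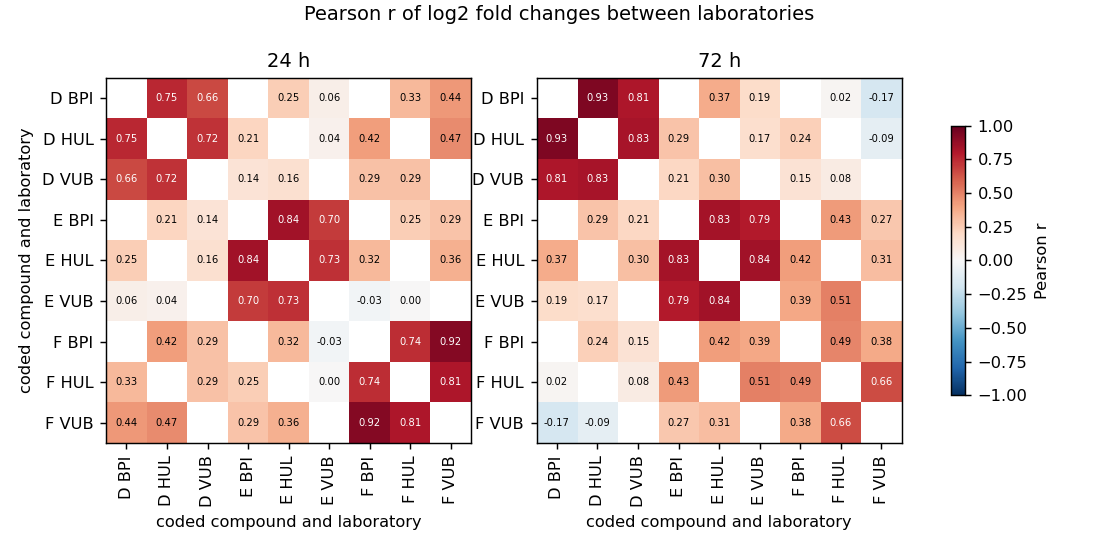
Pearson r across genes of log2 fold changes between laboratories for D, E and F at 24 h and 72 h, on a colour scale from -1 to 1, with pairs within one laboratory left blank because they share control arrays. Blocks of one compound are dark (0.66 to 0.92 at 24 h), apart from F at 72 h (0.38 to 0.66).

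Changes were also compared between laboratories gene by gene. The limma F test of equal changes called 0 genes for D, 54 for E and 268 for F at 24 h, and 698, 551 and 4 at 72 h, out of 7116 to 7494 tested. For D at 24 h, where the code as a block was supported, 22 genes passed with it, and 282 genes had an unadjusted p under 0.05 without it. In simulated data for D at 24 h this test recovered 67% of genes whose change differed 2-fold in one laboratory. The E counts were 28 and 440 without VUB treated replicate 3, and 97 at 24 h with no filter. The RMS log2 change of D at 72 h was 0.700 in BPI, 0.879 in HUL and 0.410 in VUB.

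Set against the class means of the panel, D correlated best with GTX in all 3 laboratories at both times, with r between 0.547 and 0.623 at 24 h and between 0.441 and 0.539 at 72 h. E was nearest to NC in all 3 laboratories at 24 h (0.380 to 0.415) and to GTX in all 3 at 72 h (0.418 to 0.523). With the departing pairs of the panel left out, E at 24 h was nearest to GTX in HUL (0.419, against 0.350 for NC), and in BPI NC and GTX lay at 0.377 and 0.371, while the nearest class was the same for D and F and for E at 72 h. F was nearest to GTX in all 3 at 24 h (0.271 to 0.371), and at 72 h to NC in HUL (0.491) and VUB (0.276) and to GTX in BPI (0.30). These are values across genes with no test, since the class of D, E and F is not in the labels. Such class means placed only 5 (24 h) and 7 (72 h) of the 15 panel compounds in their own class. Being nearest to a class mean therefore does not show likeness to that class.

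A comparison of the 2 times for the coded compounds was added after the data were seen. The response differed between 24 h and 72 h for 965 (BPI), 1258 (HUL) and 2034 (VUB) genes with F, and for 391, 1656 and 54 genes with D. E had 351, 79 and 0 such genes, and VUB E had 62 without treated replicate 3, while 281 genes of VUB E had an unadjusted p under 0.05. Across genes, the 24 h and 72 h changes of F correlated at 0.304 in BPI, -0.128 in HUL and -0.139 in VUB, against 0.559 to 0.663 for D and 0.690 to 0.799 for E, values whose difference was not tested. Of the 17 genes called for D in all laboratories at 24 h, 94.1% had the same sign at 72 h, and 11 were called there too, all 11 in the same direction. Of the 22 for E, 100% kept their sign and 17 were called again. Of the 742 for F, 46.5% had the same sign at 72 h, 0 were called again, and the median change in the 24 h direction went from 1.13 to -0.02 on the log2 scale.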

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

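The tests of other splits of the samples, the test of the replicate 1 pattern by compound, the limit of 2 that defines that pattern, the time differences of the coded compounds, the test of spread for F and the division of the exchange test by compound were chosen only after results were seen, and the limits of the other tests were written before their values were seen.

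Root mean square (RMS) deviations of single control arrays from their group were checked in 6 control groups, together with the response sizes of the 3 classes at both times. A value lay far from the others in 3 of these 12 groups, where about 1 in 20 is expected by chance. All 3 were control groups, out of 6. BPI control replicate 2 deviated by 0.467 at 24 h, with the next array at 0.295, and by 0.387 at 72 h, with the next at 0.279. VUB control replicate 9 at 72 h deviated by 0.448, with the next at 0.294. Without BPI control replicate 2, D at 24 h in BPI had 230 genes in place of 93.

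Responses differed between laboratories for 54 genes with E and 268 with F at 24 h, and for 698 with D, 551 with E and 4 with F at 72 h. When treated arrays, as deviations from the control mean of their own laboratory, were assigned to laboratories at random (100 assignments, the real one included), the real one alone gave as many genes for F at 24 h and for D at 72 h, with 232 and 496 as the highest other counts. For E at 72 h 4 of 100 did, with 820 as the highest. For E at 24 h it was 10 of 100 (highest 252), and for F at 72 h 9 of 100 (highest 27). The exchange ignores the codes, and the treated arrays of one laboratory share the error of its control mean. This can favour the real assignment, so chance is not called excluded for F at 24 h or D at 72 h. Neither is it for E at 72 h, where another assignment gave more genes. There the count also fell to 217 with the code as a block, where pairs were supported in BPI alone. For D at 24 h the real count was 0 (highest other 2), which every one of 100 assignments must reach, so this says nothing about chance. The counts of 252 and 27 are several times the real ones and point to a structure of the samples.

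The first pattern is the third treated array of E in VUB. Its log2 changes correlated with E in BPI and HUL at 0.023 (24 h) and 0.189 (72 h), against 0.685 to 0.816 for the other 2 arrays. An exchange with D, or with F at 24 h, is argued against by its correlation with D elsewhere of 0.210 and 0.298 at the 2 times and with F at 24 h of 0.237, where arrays of these compounds themselves reached at least 0.50. An exchange with F at 72 h stays open (0.073), because arrays of F lay as low as 0.144 there and the limits of 0.5 and 0.3 hardly test it. That lowest array was from BPI, and the F arrays of VUB itself lay at 0.338 or higher. A departure of its whole experiment code does not by itself account for this, because it stayed unlike E against the control of its own code (-0.157 at 24 h and 0.00786 at 72 h). At 72 h that code did depart: its control is the flagged control replicate 9. The treated array lay 0.226 from this control and 0.452 from the control mean (RMS). The test asks only whether that control restores the response to E, so a departing culture that did not respond stays open. The treated array was then set beside that control by distance. Its distance from that control was 1.16 times the largest between 2 controls of one code at 24 h, which leaves the question open, and 0.893 times at 72 h, so cells that were not exposed may be a candidate explanation at 72 h, and an exchange with an array outside this set, or cells that did not respond, were not tested.

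The second pattern is the departure of replicate 1 in 9 panel comparisons. Among treated arrays at 24 h, those of BEA, CsA, HQO and TRI departed alike across different controls (r 0.808 to 0.848). They correlated with their own compound at 0.063 on average, a difference of -0.770. The 4 were set together by these same correlations, which fixed the sign of the difference. A compound response seen in replicate 1 alone is therefore not decided by it. With its sign turned, the 72 h control array shared by BEA, CsA and DHP departed in the same way (mean r 0.792 with those 4 treated arrays, range 0.748 to 0.828). A departure of this kind was thus also seen without a compound, though in 1 array only. For BEN and HHC the difference was 0.242, so a stronger response to the compound in that replicate stays open there too. The test had first been run over all 9 comparisons together (-0.168) and was divided into these parts after that value was seen. A trend with expression level is argued against by a median correlation with level of 0.068. Quantile normalization left the median ratio at 2.70, from 2.69 as deposited. Since GCRMA already normalizes between arrays, a second normalization could change little, so this does not decide on the submitters' normalization. A handling or culture difference of these arrays may also remain and was not tested.

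The third pattern is F, whose response was lower at 72 h than at 24 h in each laboratory. The RMS log2 change went from 0.839 to 0.233 in BPI, from 0.62 to 0.41 in HUL and from 0.743 to 0.354 in VUB. A larger spread at 72 h could lower only the counts of called genes, and it is argued against there: with the 24 h changes set on the 72 h arrays the counts were at least 0.909 times those at 24 h, a test that replaced the ratio of standard errors (at most 1.15) set beforehand and then a comparison of the RMS values, which only restated the fall. After quantile normalization the counts of time-dependent genes were at least 0.974 times those as deposited. The values had already been normalized between arrays and could change little, so this does not decide on the normalization. A transient response to F is a hypothesis that remains. A loss of F from the medium, its dose at 72 h or cell recovery could each underlie it and were not tested.

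Time differences reached 965 genes in BPI, 1258 in HUL and 2034 in VUB for F, 391, 1656 and 54 for D, 351 in BPI and 79 in HUL for E, and 9 for HHC. Treated arrays redistributed between the times make 10 splits, too few for a share under 0.05, and the highest other counts were 2, 0 and 0 for F, 1, 0 and 5 for D, 25 and 12 for E and 0 for HHC, with the real split alone at the top (1 of 10). For E in VUB, with 0 genes, 10 of 10 splits gave as many and the highest other gave 542, which points to a structure of the samples. The other 14 panel compounds had 0 genes in the real split, a count that all 10 of 10 splits must reach.

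In the interlaboratory part the real split of treated and control arrays was the only one (1 of 84 in BPI and HUL, 1 of 100 drawn in VUB) to give as many genes in 14 of the 18 comparisons, which excludes chance under free exchange of arrays. This is not claimed for D at 24 h and E at both times in BPI, where the codes pair the samples, or for E at 72 h in VUB, where the count was 0 with controls averaged per code or limited to shared codes. Nor is it claimed for E at 24 h and 72 h and F at 72 h in HUL, or for D at 72 h in VUB. No splits within a code were run there, and controls averaged per code left 1357, 866, 134 and 590 genes. For D the real and highest other counts were 93 and 55, then 2072 and 3, in BPI, 792 and 227, then 3154 and 5, in HUL, and 994 and 212 at 72 h in VUB. For E they were 1609 and 51, then 2953 and 1, in BPI, 2350 and 30, then 1542 and 55, in HUL, and 831 and 819 at 72 h in VUB. For F they were 1887 and 5 at 24 h in BPI, 1458 and 18, then 351 and 126, in HUL, and 2316 and 119 at 24 h in VUB. Under free exchange of arrays 2 of 100 splits gave as many for D at 24 h in VUB (33, highest other 238). For F at 72 h in VUB 3 of 100 did (275, highest other 1249). Chance is not called excluded for these, since another split gave more genes and control columns averaged per code left 15 and 67. Chance cannot be excluded for F at 72 h in BPI, with 5 of 84 (1, highest other 496), or for E at 24 h in VUB, with 6 of 100 (31, highest other 1161). Where the codes pair the samples, splits that exchange arrays only within a code gave at most 0 genes. The real split was then the only one (1 of 27) to give as many for D at both times and F at 24 h in HUL and for D and F at 24 h in VUB, while the 8 such splits of D at 24 h and of E in BPI are too few for a share under 0.05. The splits with 238 and 1249 genes each set control 9 of VUB beside 1 or 2 treated arrays, that with 819 set it in place of treated array 3 of E, that with 1161 set treated array 3 beside 2 controls, and that with 496 held control 2 of BPI. Counts of 238, 1249, 1161 and 496, several times the real ones, point to a structure of the samples around these arrays.

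In the panel 10 splits of 6 arrays are too few for a share under 0.05. The real split alone was at the top (1 of 10) for HHC at 72 h (1068, highest other 0), AMQ (91 and 65, highest others 0 and 1), TAF (12 and 2, others 0 and 1), FAF at 24 h (14, other 0) and FMB at 24 h (1, other 0). For FAF and BEN at 72 h 2 of 10 splits gave as many (1 and 1, highest others 1 and 2). Where the pairs were supported, which leaves out AMQ at 72 h, the splits that part as many pairs as the real one gave at most 0 genes, and the counts of 1 and 2 came from splits that keep a pair together. In the 21 comparisons with 0 genes 10 of 10 splits must give as many. The isomers have 4 splits, also too few, and the real one stood alone (1 of 4), with 1 and 321 genes against 0. Between classes the real count was 0 in each of the 6 tests, which 100 of 100 drawn splits must reach, so these say nothing about chance. The highest others were 1, 87 and 57 at 24 h and 1, 0 and 234 at 72 h for GTX against NGTX, GTX against NC and NGTX against NC, and those of 87, 57 and 234 point to a structure of the samples that the classes do not follow.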

How the results depend on the processing

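Alternatives added after the data were seen were the fits without a departing pair or over compounds with supported pairs, with VUB E treated array 3 left out, with replicates 2 and 3 only, leaving out columns of time differences, with values under the floor set to the floor, and all settings of coded time differences. The cause was not tested unless named. Of the settings other than leave-one-out, quantile normalization left 74 of 79 results within 1.5 times or on their side of the threshold, no filter 84 of 93 and the replicate block 52 of 86. Results with no called gene in either setting count as unchanged here, and quantile normalization could change little in values already normalized between arrays. The between-laboratory similarity (0.461 to 0.543), class tests and class placements (p 0.0919 to 0.831) kept their side of the threshold in each setting, apart from 1 and 2 class calls when NMP was left out. The mean changes of the 4 named genes kept their direction with quantile normalization, the replicate block and values set to the floor (7.25, 4.68, -5.37 and -4.73), the settings run for them. Tests of gene lists, their correlation settings and class shifts were not run for lack of gene names, and averaging probe sets gave no other value because each gene has 1.

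With the replicate block, panel counts without and with it were 91 and 1537 (AMQ 24 h), 65 and 584 (AMQ 72 h, pairs not supported), 1068 and 2544 (HHC 72 h), 14 and 77, 1 and 50 (FAF), 12 and 299, 2 and 37 (TAF), 1 and 120 (BEN 72 h), 1 and 25, 0 and 986 (FMB), 0 and 194 (DLM 72 h) and 0 and 73 (HQO 72 h). Time differences went from 9 to 14 (HHC), 0 to 6 (AMQ) and 0 to 1 (FMB). The mean time difference in log10(count + 1) went from 0.09 to 0.648 (exact permutation p = 0.0625 with the block), and to 0.314 with departing pairs also left out. Interlaboratory counts with supported pairs were 364 (BPI D 24 h), 179 (BPI E 24 h), 1858 (HUL D 24 h) and 293 (VUB D 24 h). Where columns shared only a code they were 1000 (BPI D 72 h), 0 (BPI F 72 h), 2070 (VUB D 72 h), 202 (VUB E 24 h) and 0 (VUB E 72 h). Genes in all 3 laboratories were 134 (D 24 h), 0 (E 72 h) and 0 (F 72 h), and laboratory differences 22 (D 24 h), 93 and 217 (E) and 767 (F 24 h). Coded time differences were 327 (VUB D) and 1 (VUB E). ENSG00000187758 with E at 72 h had a mean of -4.953 and was not called in VUB. ENSG00000118520 lost its calls with E in BPI (adjusted p 0.204 and 0.156) and gained one with F at 72 h in VUB, and ENSG00000187758 gained one with D at 72 h in VUB, where columns shared only a code. The block moved no other count by over 1.5 times.

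With the departing pair left out and the replicate block, counts were 470 (BEA 24 h), 124 (BEN 24 h), 200 (CsA 72 h), 2 (DHP 72 h), 524 (HHC 24 h) and 1 (HQO 24 h), each from 0, while without the block all 9 such comparisons stayed at 0. Without VUB E treated array 3, genes in all 3 laboratories were 608 and 884, the laboratory difference at 24 h 28 and the VUB E time difference 62. Quantile normalization gave 54 (E 24 h) and 2 (F 72 h) in all 3 laboratories, 3 (BPI F 72 h), 73 (VUB E 24 h) and 2 (HHC 24 h). With no filter the counts were 34 (D 24 h) and 0 (F 72 h) in all 3 laboratories, 0 (BPI F 72 h), 4757 (HUL D 72 h), 221 (HUL F 72 h), 56 (VUB D 24 h), 4 (FAF 24 h), 97 (laboratory difference, E 24 h) and 178 (isomers 72 h).

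Control arrays averaged per code, which leaves fewer samples, gave 233, 1357, 866, 722 and 134 genes for HUL D 24 h, E 24 h, E 72 h, F 24 h and F 72 h, and 15, 590, 0, 0 and 67 for VUB D 24 h, D 72 h, E 24 h, E 72 h and F 72 h. Controls of shared codes alone gave 20, 1209, 295 and 1666 for BPI D 24 h, D 72 h, E 24 h and E 72 h, and 55, 0 and 0 for VUB D 24 h, E 24 h and E 72 h. For the isomers, the fit with no replicate block and the direct comparison each gave 0 and 0.

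Leaving out one column at a time gave ranges of 14 to 54 and 12 to 106 (AMQ), 340 to 1123 (HHC 72 h), 0 to 30 (HHC 24 h), 1 to 13 and 1 to 8 (FAF), 4 to 9 and 1 to 3 (TAF), 0 to 3 and 0 to 7 (FMB), 0 to 1 (BEN 72 h) and 0 to 1 (HQO 72 h). Ranges were 28 to 230, 1346 to 2228 and 0 to 18 for BPI D 24 h, D 72 h and F 72 h, and 455 to 716, 1502 to 2839, 924 to 1800 and 70 to 437 for HUL D 24 h, E 24 h, E 72 h and F 72 h. For VUB they were 14 to 82 and 373 to 1453 (D), 0 to 1233 and 0 to 2309 (E) and 82 to 1079 (F 72 h). Class tests of GTX at 24 h ranged from 0 to 2 against NGTX and from 0 to 1 against NC, and isomers from 2 to 181 and 0 to 718. Time differences ranged from 2 to 24 (HHC), 193 to 476 (BPI D), 587 to 1276 (BPI F), 31 to 316 (HUL E), 10 to 56 (VUB D) and 0 to 144 (VUB E).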

Other observations

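The comparison of coded with panel compounds was chosen after the data were seen, and its first test was replaced. Drawing the nearest panel compound evenly from 15 had given a very small p, but the panel compounds are not equally likely to be nearest, so coded names were rearranged within laboratories in its place. The shares of genes with one direction are descriptions: the panel compounds were picked by correlations over genes that include these, so the limits written for the shares decide nothing.

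Coded and panel arrays share no controls, so their responses can be set side by side. At 72 h the panel compound nearest to D was AMQ in each laboratory (r across 6654 genes 0.677 in BPI, 0.679 in HUL and 0.646 in VUB), with TAF second. At 24 h, across 6554 genes, D was nearest to AMQ in BPI (0.745) and to TAF in HUL (0.644) and VUB (0.611). E was nearest to HHC in each laboratory at 72 h (0.477 to 0.567). At 24 h it was nearest to BEN in each laboratory (0.490 to 0.546), but this rests on the departing replicate 1 array of BEN: without the departing pairs its correlation with BEN was 0.191 in BPI, 0.255 in HUL and 0.355 in VUB, and the nearest compound was FAF in BPI and HHC in HUL and VUB. One panel compound was nearest in all 3 laboratories in 3 of 6 settings, with a one-sided exact p of 0.00617 over 1296 rearrangements. This tests whether the laboratories share a nearest compound, and not how alike the coded and panel compounds are. For F the nearest compound varied, with AMQ, ACE and AMQ at 24 h and HHC, BEN and BEN at 72 h. Without the departing pairs it was HQO in each laboratory at 24 h (0.433 to 0.541), so that again 3 of 6 settings had one nearest compound (exact p = 0.00617), with F in place of E at 24 h.

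Of the 774 genes called for D in all laboratories at 72 h, 750 were tested with AMQ, and 94.7% of them moved in the same direction, against 85.5% with TAF and a median of 36.3% over the 15 compounds. Of these, 240 were called with AMQ in the block fit, all in the same direction, against 29.0 expected from independent lists, although the pairs of AMQ at 72 h did not meet the criterion. With HHC 86.6% of the 72 h genes of E shared their direction, against a median of 52.2% over the 15 compounds, and 313 were called in the same and 23 in the opposite direction (85.6 expected in the same). With BEN 90.5% of the 24 h genes of E shared it, over 21 genes, with DHP next at 85% and a median of 70% over the 15 compounds, and 0 were called. Without the departing pairs HHC led with 95% and BEN had 85.7%, so a likeness of E and BEN at 24 h stays open. The 24 h genes of D shared direction with TAF for 100% of 16 genes, but AMQ and FAF also reached 100%, so this decides nothing between them; it had first been read as evidence against TAF because AMQ was listed ahead in the tie. These values say nothing about the identity of D.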
